A study of Cucumis sativus with 33 samples.

How the data were processed

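RNA-seq libraries were made from corollas of female cucumber flowers, 3 for each of 11 groups defined by ovary type and day after labeling. Per the labels' protocols, 5 corollas were ground and mixed for each replicate, RNA integrity was checked, and libraries were made by standard Illumina protocols. The series' design text calls the replicates biological. Whether the pools came from separate plants, harvests or sequencing runs is not given in the sources used here, so the p-values measure the spread between these pools. Samples were grouped by ovary type and day from their labels, and stages were taken from the design text.

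The authors deposited a single table of 33 columns, 1 per library, and the name they gave it calls the values RPM, the reads of a gene relative to the library total. Per the submitters' processing notes, TopHat and HTSeq were used. Their versions, the genome build and the annotation are not given in the sources used here. No column belonged to another sample. Each column summed to between 999976 and 1000019 RPM and no value was 0. The lowest value in each column, 0.04 to 0.06 RPM, was held by 2720 to 3489 genes (11.7% to 15.0%).

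The low values of each column were whole multiples of a single step, from which library totals were recovered. In each of the 33 libraries 100% of values came out within 0.25 of a whole read. The lowest step was taken as a gene with no read to which 1 had been added, because no value was 0. The spread of low steps did not settle this. It was examined in genes with 2 steps above the lowest value in total over the 3 libraries of a group. Both steps lay in 1 library 0.59 times as often as in 2 libraries with 1 step each. With 1 read added to every value 0.5 would be seen. The ratio for a lowest step of 1 real read was not set beside it, so 0.59 does not decide. Reads were counted as steps minus 1 on this assumption, on which the edgeR test and the ratios from summed reads rest. The RPM values were used as deposited. For 30 libraries the recovery also passed a separate test on the lowest values. For N5 replicate 2, S1 replicate 2 and S4 replicate 2 it did not, and these 3 were left out of the edgeR test and of the ratios from summed reads. They were kept in the comparison of replicate pairs. Totals ran from 16858673 to 24643175 reads. On this assumption these totals include the 1 read added to each gene. A limit of 3 reads corresponds, with the added read, to a deposited value of 0.162 to 0.237 RPM per library. Intervals and limits from reads cover counting error only, since reads amplified by PCR are not independent molecules.

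Replicate libraries were compared before averaging. No 2 libraries were identical, and the reads of every replicate pair differed by far more than sampling noise, with a chi-square per degree of freedom of 5.2 to 74.61 over genes with at least 20 reads.

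Gene identifiers were used as the file gives them. A table of 23999 RefSeq genes was searched for names, and 0 of the 23248 identifiers matched. The file does not pair identifiers with names either. The 28 lists of genes by function or tissue that had been fixed before the data were examined rest on gene descriptions, so they could not be formed and no list was tested. For the same reason the text names 2 genes that rose and 2 that fell. The rule for named genes, also fixed beforehand, took the called genes with the largest change among those with a mean of 10 RPM or more in the higher group and no overlap between the libraries of the compared sides, and with no names to join it allowed 2 identifiers per direction. They were taken from N5 against N1 and followed through the other comparisons.

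The test was limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with all 33 libraries in 1 fit of 11 group means and moderated variances with a mean-variance trend. The 18905 genes with a mean of 1 RPM or more in at least 1 group were tested, two-sided, and p-values were adjusted by Benjamini-Hochberg within each of the 12 comparisons. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. For genes with few reads, ratios were also taken from summed reads, with exact 95% intervals. Overlaps of calls are given with the number that independent lists of the same sizes would share among the 18905 genes. The nearest normal group of a super library was the one whose mean had the highest Pearson correlation with it. The progress index, the overlaps and the sets of genes with a peak or minimum in the yellow bud were defined after the data were seen. Those sets hold the genes called, by the same test and limits, in opposite directions from N3 to N4 and from N4 to N5, and a gene's maximum or minimum in the super course is the group with its highest or lowest mean.

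Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPM, rescaling by the median of gene ratios, fits of the compared groups alone, variances without a trend, the replicate number as a block, an adjusted p of 0.01, and leaving out each library in turn. The edgeR quasi-likelihood test (version 4.0.16, TMM scaling) was run on the recovered reads of the 30 libraries as a further one. It called 8784 genes in N5 against N1, of which 6933 were also called by limma in the same direction, and 9783 in S9 against S1, of which 7850 were. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

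The test was also run on simulated data for N5 against N1. Reads were drawn from the means, totals and dispersions of the real libraries, with 50 genes changed at each of 4 sizes, and 18806 genes passed the filter. The changed genes were taken from those with a mean above 2 RPM in N1. The shares called therefore do not cover lower genes, whose changes log2(RPM + 1) understates. The test called 96% of genes changed 3-fold up, 90% of those lowered to 0.33 of their level and 100% of those changed 8-fold, and 0 of those changed 1.5-fold, which lies under the 2-fold limit. Of the unchanged genes, 2 were called. The N5 means of all other genes were set to those of N1, so a shift of the median gene was not simulated.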

Results

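Corollas of female cucumber flowers (Cucumis sativus, inbred line 6457) were profiled by RNA-seq while the bud opened, with the flowers bagged against pollination. The corolla is the whorl of petals, and its opening is anthesis. Plants had received either of 2 treatments. Under the first, with ample fertilizer and water and a single fruit left near the growing point, they bore what the labels call super ovaries. Under the second, with fertilizer and water in short supply and fruits set elsewhere on the plant, they bore normal ovaries. Days were counted from the labeling of the ovary once it was visible. The normal course was sampled on days 1, 3, 4 and 5 (N1, N3, N4 and N5), when its corollas were typically green buds (day 1), green yellow buds (day 3), yellow buds (day 4) and open flowers (day 5). The super course was sampled on day 1 (S1, green bud), days 3, 4 and 5 (S3, S4 and S5, green yellow bud), days 7 and 8 (S7 and S8, yellow bud) and day 9 (S9, flowering). Most normal flowers opened on day 5 and most super flowers on day 9. Each of the 11 groups had 3 libraries, and each library pooled 5 corollas.

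Values were deposited as RPM, the reads of a gene relative to the library total, for 23248 genes in 33 libraries. The totals recovered from the value steps ran from 16858673 to 24643175 reads per library, with a median of 19735277, and 1 read was worth 0.0406 to 0.0593 RPM. The 10 most abundant genes held 3.21% to 7.19% of a library, with the highest shares in N4 (6.64% to 7.19%). Of the genes, 18905 reached a mean of 1 RPM in at least 1 group and were tested. The first principal component held 61.9% of the variance of their log2(RPM + 1) values and the second held 15.4%. Replicate libraries correlated across genes at 0.989 or above, except S7 replicate 3, which reached 0.965 and 0.977 with S7 replicates 1 and 2.

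**Figure D1:**
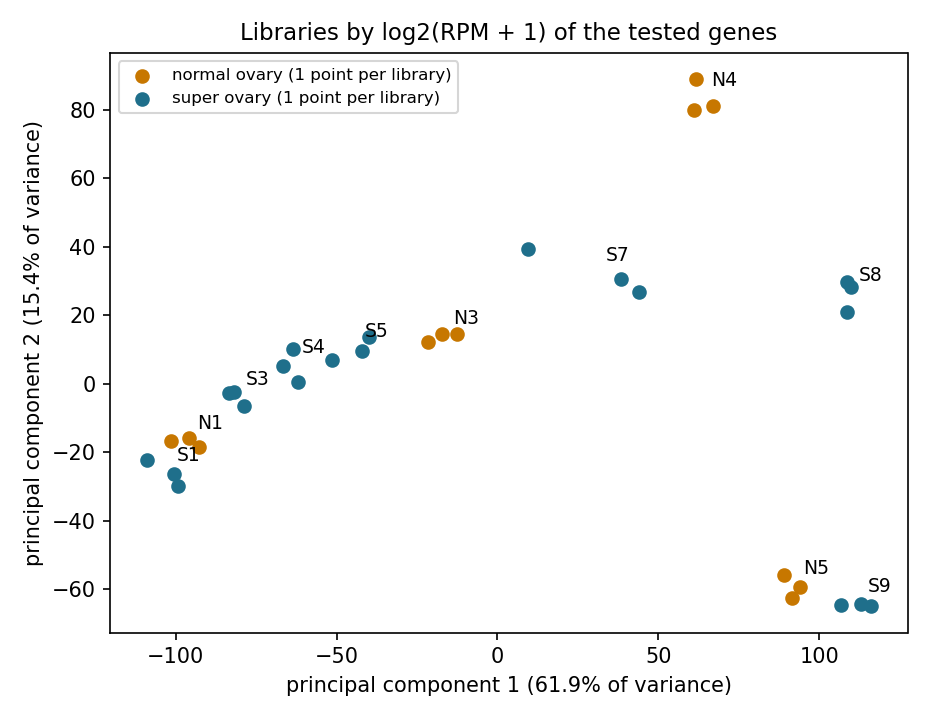
Each point is 1 of the 33 libraries, placed by its scores on the first (61.9% of variance, horizontal) and second (15.4%, vertical) principal components of log2(RPM + 1) over the 18905 tested genes, in arbitrary score units, with normal and super ovaries in different colors and the group written beside its 3 libraries. The S1 libraries lie beside N1 and the S9 libraries beside N5. S3, S4, S5 and N3 follow in that order along the first component, and N4 lies highest on the second.

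The first question was which genes change while the corolla of a normal ovary opens. Between the green bud and flowering, 2840 genes rose and 4983 fell in N5 against N1, which is 41.4% of the genes tested. Among them, 1126 rose and 1576 fell by 4-fold or more. Gene Csa6G151640 stood at 0.14 ± 0.021 RPM (SD, n = 3) in N1, 0.71 ± 0.10 in N3 and 2.09 ± 0.48 in N4, and then reached 303 ± 11.4 RPM in N5. Counted as steps minus 1, it had 1 or 2 reads per N1 library. Its ratio of N5 to N1 was then 3386, with a 95% exact interval of 1451 to 10430 from 11951 reads in 2 libraries against 5 reads in 3. Gene Csa3G872170 rose earlier, from 3.28 ± 0.069 RPM in N1 to 163 ± 12 in N3 and 2656 ± 249 in N4, and stood at 1579 ± 27.4 in N5. Gene Csa3G026150 fell from 297 ± 50.7 RPM in N1 to 152 ± 27.7 in N3, 10.1 ± 1.6 in N4 and 0.65 ± 0.0058 in N5. Gene Csa7G414480 lost most of its level before day 3, going from 160 ± 11.3 RPM in N1 to 21 ± 2.68 in N3, 5.21 ± 0.085 in N4 and 0.55 ± 0.14 in N5. On the log2(RPM + 1) scale, which understates the change of low genes, limma gave Csa3G872170 a change of 8.53 (SE 0.14, adjusted p 1.3e-25) and Csa6G151640 one of 8.05 (SE 0.13, adjusted p 3.7e-26). Csa3G026150 changed by -7.49 (SE 0.13, adjusted p 3.0e-25) and Csa7G414480 by -6.70 (SE 0.27, adjusted p 3.6e-18).

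The excess of falling genes depended on the scaling. As deposited, the median gene changed by -0.30 on the log2 scale from N1 to N5 and 36.3% of the called genes rose. After rescaling each library by the median of its gene ratios, 3764 genes rose and 3595 fell, so that 51.1% of the calls were rises.

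The same question was asked of super ovaries with S9 against S1. There 3173 genes rose and 5731 fell, 47.1% of those tested, of which 1369 and 2054 changed by 4-fold or more. The genes were largely those of the normal course. Of the 2840 genes that rose in normal ovaries, 2396 (84.4%) rose in super ovaries, where independent lists would share 476.7. Of the 4983 that fell, 4535 (91%) fell in super ovaries, against 1510.6 for independent lists. The means of these comparisons have no library in common, though the fit shared the variance of each gene over all libraries. Genes that rose in one course and fell in the other numbered 13, or 40 with a pseudocount of 0.1, 6 with one of 5 and 41 by edgeR. Csa6G151640 went from 0.12 ± 0.021 RPM in S1 to 238 ± 54.3 in S9, a ratio of 3144 with a 95% exact interval of 1075 to 15245 from 13350 reads in 3 libraries and 3 reads in 2. Csa3G872170 passed from 4.92 ± 1.55 RPM in S1 through 2051 ± 175 in S8 to 1407 ± 77.5 in S9. Csa3G026150 went from 240 ± 30 RPM in S1 to 0.35 ± 0.21 in S9, a level 828 times lower by its reads, with a 95% exact interval of 517 to 1422. Csa7G414480 went from 163 ± 23.5 to 0.69 ± 0.40 RPM, or 264 times lower with an interval of 193 to 374. These intervals cover counting error only and rest on reads counted as steps minus 1. Rescaling turned the split of the calls from 35.6% to 51.2% rises (4324 up and 4121 down), the median gene having changed by -0.35 as deposited.

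**Figure D2:**
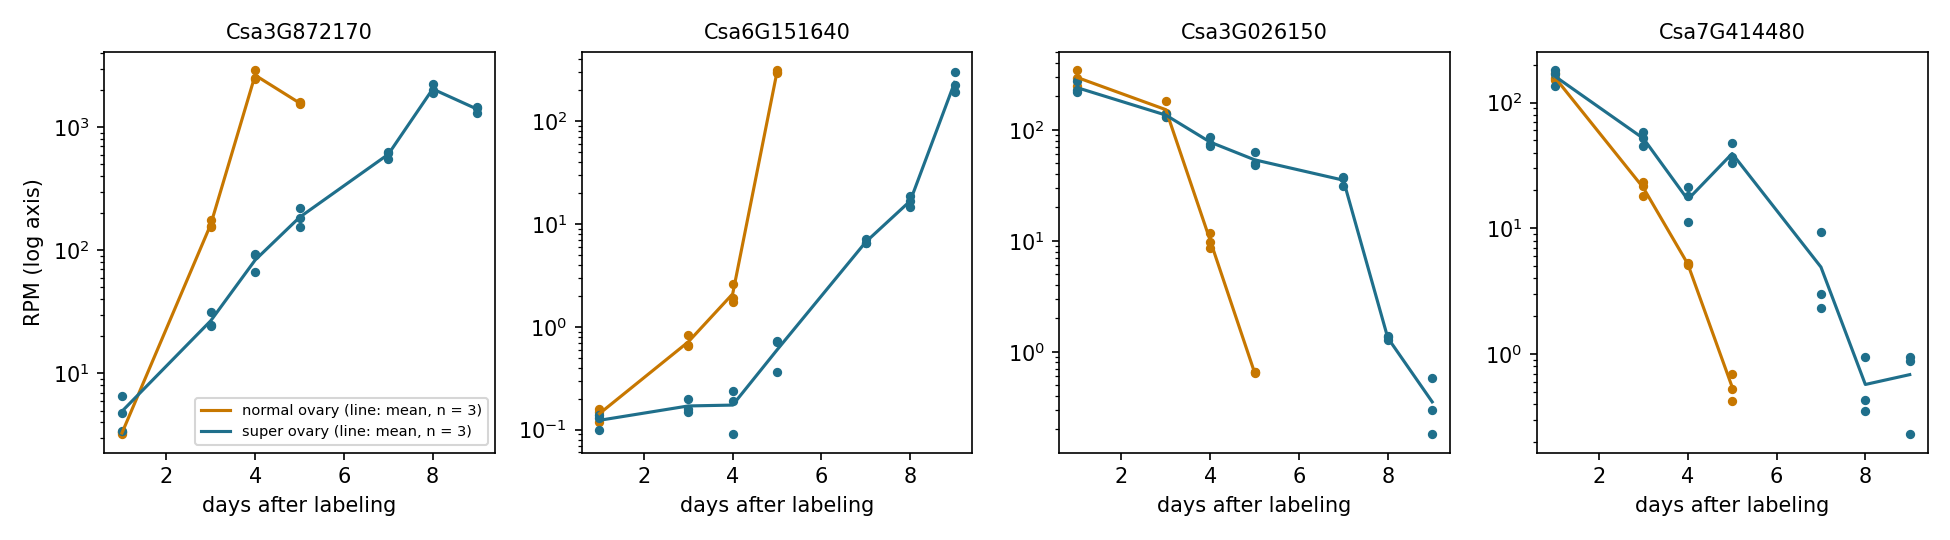
RPM on a log axis against days after labeling for the 4 genes named by their identifiers, with normal and super ovaries in different colors, a point for each library and a line through the means of 3 libraries. Csa3G872170 and Csa6G151640 climb and Csa3G026150 and Csa7G414480 drop in both courses, by day 5 in normal and day 9 in super ovaries, with Csa7G414480 higher in S5 (39.3 RPM) than in S4 (16.9 RPM).

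Whether the change over opening itself differed between the ovary types was tested as an interaction. The change was more positive in super ovaries for 602 genes and more negative for 623, together 6.5% of the genes tested. The split was 602 to 623 as deposited and 707 to 547 after rescaling. Among the 602, 212 rose in both courses, 238 rose in super ovaries and were not called in normal ones, and 66 fell in normal ovaries and were not called in super ones. Among the 623, 222 fell in both courses, 181 fell in super ovaries and were not called in normal ones, and 92 rose in normal ovaries and were not called in super ones. The 13 genes that moved in opposite directions in the 2 courses were all among the interaction calls. By construction the interaction is the difference at flowering minus the difference at the green bud. Of the 602 and 623 genes, 436 and 299 were also called in S9 against N5, and 24 and 151 in S1 against N1. All of this sorting uses the libraries of the interaction test and is not independent of it. None of the 4 genes named here was called, the interaction of Csa3G872170 being -0.60 (SE 0.20, adjusted p 0.025), under the 2-fold limit. With a pseudocount of 5 the interaction count was 627.

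At the green bud stage on day 1, the ovary types differed in few genes. In S1 against N1, 184 genes were higher and 51 lower, 1.2% of those tested, and of the higher genes 45 differed by 4-fold or more. Csa7G414480 stood at 163 ± 23.5 RPM in S1 and 160 ± 11.3 in N1, and none of the other named genes was called either. The count was 394 with a pseudocount of 0.1 and 87 with one of 5, and edgeR on recovered reads called 370.

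On day 3, when both types were at the green yellow bud stage, 1323 genes were higher and 976 lower in S3 than in N3. Csa3G872170 stood at 26.8 ± 4.25 RPM in S3 against 163 ± 12 in N3, a log2 difference of -2.57 (SE 0.14, adjusted p 4.0e-13 by limma). Csa7G414480 was still at 51.9 ± 6.6 RPM in S3 when it had come down to 21 ± 2.68 in N3 (log2 difference 1.27, SE 0.27, adjusted p 2.5e-04). Csa3G026150, at 136 ± 4.91 RPM in S3 and 152 ± 27.7 in N3, was not called. Rescaling changed which side had more genes, to 867 higher and 1271 lower (57.5% against 40.6% higher), with a median gene at 0.17 as deposited. A pseudocount of 5 gave 1274 genes.

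Day 4 set green yellow buds of super ovaries against yellow buds of normal ones, and it showed the largest number of differences of the day-matched comparisons, with 5649 genes higher and 1316 lower in S4 than in N4. Csa3G872170 stood at 83.5 ± 14.6 RPM in S4 against 2656 ± 249 in N4 (log2 difference -4.99, SE 0.14, adjusted p 7.3e-21). Csa3G026150 kept 77.5 ± 7.05 RPM in S4 against 10.1 ± 1.6 in N4 (log2 difference 2.83, SE 0.13, adjusted p 1.3e-16). The direction of the remainder rested on the scaling, since 81.1% of the calls were higher in S4 as deposited and 50.5% after rescaling (2852 higher and 2801 lower). The median gene was 0.50 higher in S4 as deposited. With a pseudocount of 5, 4424 genes were called.

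By day 5 the normal flowers were open and the super corollas were still green yellow buds. In S5 against N5, 3893 genes were higher and 2087 lower, and most of them were genes that changed between S1 and S9 in the super course. Of the 3893 higher genes, 3118 (80.1%) fell between S1 and S9, where independent lists would share 1180.2, and 119 rose. Of the 2087 lower genes, 1728 (82.8%) rose between S1 and S9, where independent lists would share 350.3, and 12 fell. Neither S5 nor N5 enters the means of S9 against S1, though the fit shared the variance of each gene. Csa6G151640 stood at 0.60 ± 0.21 RPM in S5 against 303 ± 11.4 in N5 (log2 difference -7.58, SE 0.13, adjusted p 9.1e-26), and Csa3G872170 at 186 ± 32.3 against 1579 ± 27.4. Csa3G026150 was at 53.7 ± 7.81 RPM in S5 (log2 difference 5.04, SE 0.13, adjusted p 2.0e-21) and Csa7G414480 at 39.3 ± 7.84 (log2 difference 4.69, SE 0.27, adjusted p 1.5e-14). The share of calls that were higher in S5 was 65.1% as deposited and 45.9% after rescaling (2491 higher and 2935 lower), with the median gene at 0.31. Under rescaling 1921 genes were higher in S5 and fell over the super course, and with a pseudocount of 5 there were 1812 of them and 3908 calls.

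Yellow buds were compared at the stage matched by name, with the mean of S7 and S8 against N4. The first flowers opened on day 4 in the normal and day 8 in the super course, the days of N4 and S8. On the progress index defined below, S7 (0.59) and S8 (0.92) lay on either side of N4 (0.66). Position on the course was thus not separated from ovary type in this comparison. Here 1618 genes were higher and 582 lower in super ovaries, 11.6% of those tested, and 401 and 65 of them differed by 4-fold or more. Genes that rose into the normal yellow bud and fell after it mostly had their maximum at that stage in super ovaries. Called higher in N4 than in N3 and lower in N5 than in N4 were 550 genes, of which 348 (63.3%) had their highest super group mean in S8 and 65 in S7, together 75.1%. The share was 16.1% among the 5245 other genes called in either of those normal steps. After rescaling the set held 899 genes and the shares were 78.1% and 25.8%. The 1452 genes called lower in N4 than in N3 and higher in N5 than in N4 had their lowest super mean in S7 or S8 for 46.4%, against 33.9% of the other genes called, and after rescaling 884 genes had it there for 28.6% against 21.7%. Over all tested genes this share was 40.3% as deposited and 30.6% after rescaling. The set thus lay little above the general share as deposited and under it after rescaling, and a shared minimum was not shown. Csa3G872170, at 2656 ± 249 RPM in N4, was at 605 ± 42 RPM in S7 and 2051 ± 175 in S8, and its mean over the 2 groups was lower (log2 difference -1.25, SE 0.12, adjusted p 2.4e-09). Csa7G414480 was lower too, at 4.92 ± 3.92 RPM in S7 and 0.57 ± 0.32 in S8 against 5.21 ± 0.085 in N4 (log2 difference -1.13, SE 0.24, adjusted p 1.7e-04). Csa6G151640 was already at 6.70 ± 0.41 RPM in S7 and 16.8 ± 2.11 in S8 against 2.09 ± 0.48 in N4 (log2 difference 1.93, SE 0.11, adjusted p 8.7e-14). Rescaling brought the higher share from 73.5% to 56.5% (1273 higher and 980 lower), with the median gene at 0.14 as deposited. A pseudocount of 5 gave 1222 genes, and edgeR on recovered reads gave 3375.

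At flowering, 4 days apart as counted from labeling, S9 and N5 differed in 553 higher and 426 lower genes, 5.2% of those tested. Of these, 118 and 41 differed by 4-fold or more. Csa3G872170 stood at 1407 ± 77.5 RPM in S9 and 1579 ± 27.4 in N5, and Csa6G151640 at 238 ± 54.3 and 303 ± 11.4, and neither they nor the falling pair were called. The green bud differences were mostly other genes. Of the 235 genes called in S1 against N1, 20 were called in the same direction at flowering and 25 in the opposite one. The means of these 2 comparisons share no library, though the fit shared the variance of each gene. Independent lists would share 5.4 genes that were higher in both and 1.1 that were lower in both, where 12 and 8 were seen. For opposite calls, 20 genes were higher in S1 and lower in S9, against 4.1 for independent lists, and 5 were lower in S1 and higher in S9, against 1.5. The same and opposite calls numbered 55 and 47 with a pseudocount of 0.1, 3 and 5 with one of 5, and 53 and 44 by edgeR. Which of them was larger thus depended on the setting. The flowering count ranged from 488 with a pseudocount of 5 to 1574 with one of 0.1, and edgeR on recovered reads called 1633.

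**Figure D3:**
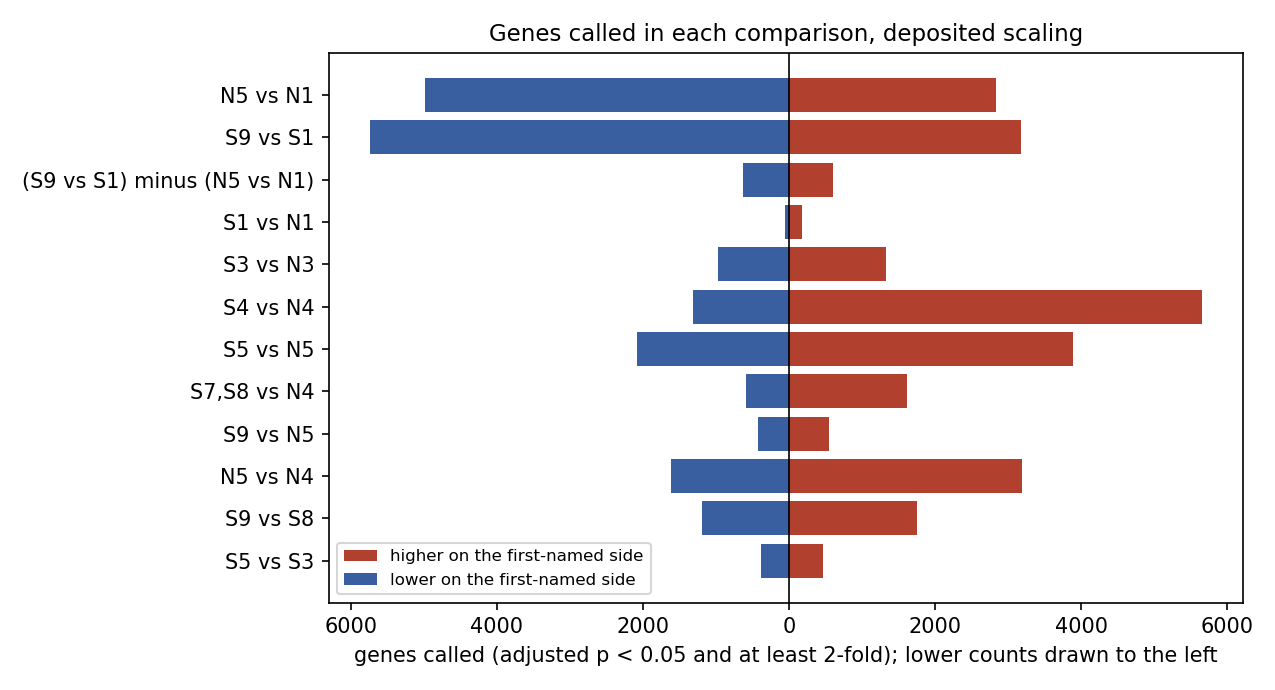
Bars give the number of genes called by limma in each of the 12 comparisons (adjusted p under 0.05 and at least 2-fold, deposited scaling), with genes higher on the first-named side drawn to the right of 0 and lower genes to the left. The day-matched contrasts S4 vs N4 and S5 vs N5, with 6965 and 5980 genes, stand above the stage-matched contrasts S9 vs N5 (979) and S1 vs N1 (235).

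The last step into flowering was compared within each course. From the yellow bud to the open flower, 3188 genes rose and 1611 fell in N5 against N4, and 1755 rose and 1191 fell in S9 against S8. These steps did not start at the same point of the course. On the progress index defined below, N4 stood at 0.66 and S8 at 0.92, so the super step covered less of it. Csa6G151640 rose in this step by 6.63 on the log2 scale (SE 0.13, adjusted p 6.0e-24) in normal ovaries and 3.73 (SE 0.13, adjusted p 4.7e-19) in super ovaries. Csa3G872170 changed by -0.75 and -0.54 on the log2 scale, under the 2-fold limit, though edgeR on recovered reads put the normal step at -1.02 (adjusted p 1.1e-05), past it. Csa3G026150 fell in normal ovaries (-2.74, SE 0.13, adjusted p 5.3e-16). From S8 to S9 it went from 1.33 ± 0.057 to 0.35 ± 0.21 RPM, a change of -0.80 on the log2(RPM + 1) scale that was not called, and of -2.22 (adjusted p 5.1e-05) by edgeR on recovered reads, which was. The difference between these last steps was not tested. In the normal step the share of rising genes was 66.4% as deposited and 52.1% after rescaling (2478 up and 2280 down), with the median gene at 0.20. A pseudocount of 5 gave 3114 and 1794 genes for the normal and super steps.

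Within the green yellow bud stage of super ovaries, which lasted from day 3 to day 5, expression continued to change. In S5 against S3, 463 genes rose and 383 fell, 4.5% of those tested. Csa3G872170 went from 26.8 ± 4.25 to 186 ± 32.3 RPM (log2 change 2.74, SE 0.14, adjusted p 2.3e-13), and Csa3G026150 from 136 ± 4.91 to 53.7 ± 7.81 (-1.33, SE 0.13, adjusted p 1.6e-08). Csa7G414480 went from 51.9 ± 6.6 to 39.3 ± 7.84 RPM and was not called. The count was 379 with a pseudocount of 5, 1387 with one of 0.1 and 1469 by edgeR on recovered reads.

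Each super library was also placed on the normal course by its correlation across genes with the normal group means, where genes are not independent replicates. The S1, S3 and S4 libraries, 9 in all, were nearest to N1. All 6 libraries of S5 and S7 were nearest to N3. In S8, 2 libraries were nearest to N4 and 1 to N5, at mean correlations of 0.935 ± 0.0065 and 0.933 ± 0.0018 (SD, n = 3), and the S9 libraries were nearest to N5 (0.972 ± 0.0067). S4 stood almost between groups, at 0.953 ± 0.0007 with N1 and 0.947 ± 0.0044 with N3. With a pseudocount of 0.1, 0 libraries were nearest to N4.

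A progress index, defined after the data were seen, placed the libraries on a continuous scale. It is the projection of a library on the line from N1 (0) to N5 (1) over the 7823 genes called between them. The normal course passed through 0.39 ± 0.020 in N3 and 0.66 ± 0.015 in N4 (SD, n = 3). The super course stood at -0.01 ± 0.027 in S1, 0.11 ± 0.014 in S3, 0.20 ± 0.012 in S4, 0.29 ± 0.028 in S5, 0.59 ± 0.084 in S7, 0.92 ± 0.001 in S8 and 1.04 ± 0.018 in S9. On days 3, 4 and 5 the super corollas lay behind the normal ones by many times these spreads, and S9 lay slightly past N5. The index and the correlations did not place all groups alike, since by the index 2 libraries of S4 were closest to N3, 2 of S7 to N4 and all 3 of S8 to N5. The wide spread in S7 came from replicate 3, and the index of that group was 0.64 without it.

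**Figure D4:**
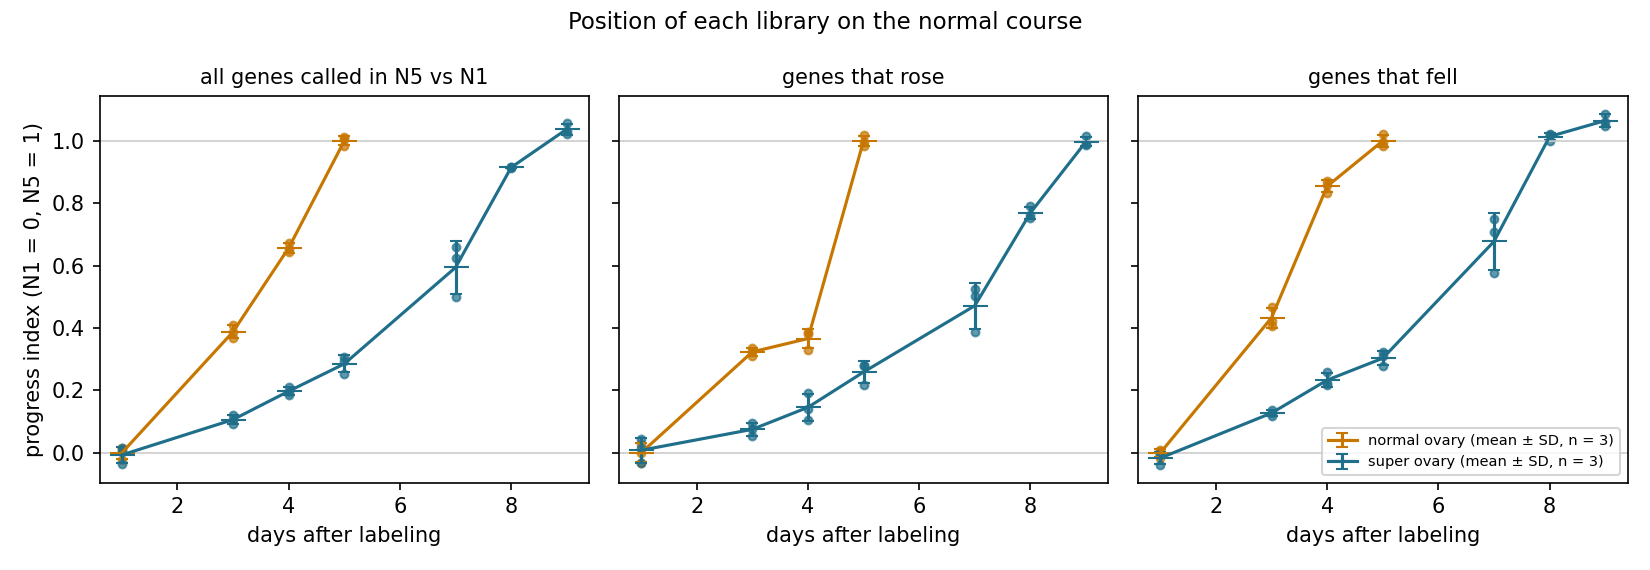
Progress index, a unitless position between N1 (0) and N5 (1), against days after labeling for all genes called in N5 vs N1 (left), those that rose (middle) and those that fell (right), with a point per library and lines with bars for the mean and SD of 3 libraries. The super course stays at or under 0.29 to day 5 over all genes and reaches 0.92 on day 8, when the normal course has reached 1 on day 5.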

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

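The counts of splits in this part were set before their results were seen. The change over opening differed between super and normal ovaries in 1225 genes by the interaction test, and a difference between groups is what drew attention to it. Of 100 splits of the libraries drawn at random, 1, the real one, gave as many genes. The splits exchanged super and normal libraries within flowering and within the green bud. They therefore test for a difference between the ovary types at either end, and cannot decide whether the change over opening differs. The highest other split gave 1191 genes. It had kept S9 and N5 apart and mixed only S1 with N1. Where both ends were mixed, the highest was 5 genes.

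For the mean of S7 and S8 against N4, 1 of 84 splits, the real one, gave as many as 2200 genes. S7, S8 and N4 were distinct from each other, and mixing their libraries widens the spread within groups. The rank therefore does not decide whether N4 differs from the super yellow buds as such. The highest other gave 1980 and exchanged whole groups, N4 for a super yellow bud group, and those that mixed libraries gave at most 983. The remaining comparisons set 3 libraries against 3, which makes 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, reached the real count. It was 7823 in N5 against N1, 8904 in S9 against S1, 2299 in S3 against N3, 6965 in S4 against N4, 5980 in S5 against N5 and 979 in S9 against N5, where the highest other was 0. It was 235 against 12 for the highest other in S1 against N1, 4799 against 7 in N5 against N4, 2946 against 48 in S9 against S8 and 846 against 16 in S5 against S3.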

How the results depend on the processing

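The alternatives for the overlaps, the yellow bud sets and the progress index, and Spearman correlation for the nearest group, were chosen after seeing the data. In the 344 alternative fits of the 4 named genes for 5 comparisons (N5 against N1, S9 against S1, S5 against N5, S9 against N5 and the interaction), each call kept its direction and each gene its side of the threshold. These genes were picked for their large change in N5 against N1. In other comparisons some of their calls differed by edgeR. Csa6G151640, not called by limma, was at -2.61 (adjusted p 3.1e-05) in S3 against N3 and 2.12 (adjusted p 0.001) in S5 against S3 by edgeR. Values near 0 that were not called changed sign, the interaction of Csa3G026150 being 0 as reported, -0.52 at a pseudocount of 0.1, 0.22 at 5 and -0.68 by edgeR, and Csa7G414480 in S9 against N5 going from 0.10 to -0.02 without S9 replicate 2. The side with more calls turned under rescaling in N5 against N1, S9 against S1, S3 against N3, S5 against N5, S5 against S3 (396 higher and 405 lower) and the interaction. It also turned at a pseudocount of 5 in S3 against N3 (606 higher and 668 lower), S5 against S3 (188 and 191) and the interaction (342 and 285), by edgeR in S3 against N3 (1542 and 1706), and for the interaction without N1 replicate 3 (649 and 605), N5 replicate 3 (632 and 631) or S1 replicate 1 (605 and 564). The alternatives set for gene lists were not run, because no list could be formed. A pseudocount of 5 gave 627 genes for the interaction, 87 for S1 against N1, 1274 for S3 against N3, 4424 for S4 against N4, 3908 for S5 against N5, 1222 for S7 and S8 against N4, 488 for S9 against N5, 3114 for N5 against N4, 1794 for S9 against S8 and 379 for S5 against S3. It also left 6 genes with opposite changes over opening, 3 with the same and 5 with opposite calls at green bud and flowering, and 1812 that were higher in S5 than in N5 and fell over the super course. One of 0.1 gave 394 genes for S1 against N1, 1574 for S9 against N5, 1387 for S5 against S3, 40 with opposite changes, 55 with the same and 47 with opposite calls, and 0 libraries nearest to N4. A pseudocount shrinks or widens the fold changes of low genes by construction, and beyond that the cause was not tested. The edgeR test on recovered reads gave 370 genes for S1 against N1, 3375 for S7 and S8 against N4, 1633 for S9 against N5, 1469 for S5 against S3, 3715 normal risers that rose in super ovaries, 41 with opposite changes, 53 with the same and 44 with opposite calls, and 2752 genes lower in S5 than in N5 that rose over the super course. Of these differences too the cause was not tested. Rescaling gave 1921 genes higher in S5 that fell. It lowers S5 values relative to N5 and raises S9 values relative to S1. Both lists shrank, to 2491 genes higher in S5 and 4121 that fell from S1 to S9, and their parts in the overlap were not separated. For the yellow bud sets, its effect on N4 and S8 matters. Rescaling also gave 899 genes that rose into N4 and fell after (550 as reported) and 884 that fell into N4 and rose after (1452), of which 28.6% and not 46.4% had their minimum in S7 or S8, since it raises N4 and S8 relative to other groups.

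The fits with the replicate number as a block changed no call count by over 1.5 times (1228 genes for the interaction, 237 for S1 against N1). No clear pairing of the libraries by number was seen. Deviations of libraries with the same number correlated by -0.29 to 0.37, with a mean of 0.01 against -0.01 for different numbers. Of 33 libraries, 15 correlated best with their own of the 3 numbers, which does not exclude a weak pairing. Leaving out each library in turn moved no count by over 1.5 times, with 7724 to 7895 genes in N5 against N1, 1119 to 1419 for the interaction, 209 to 285 in S1 against N1 and 853 to 1149 in S9 against N5. Without S7 replicate 3, S7 and S8 against N4 gave 2287 genes. Depth limits what can be said under deposited values of 0.162 to 0.237 RPM, the level of 3 reads with the added one.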

Other observations

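The 4 tests on the order of the super groups and the test of single libraries in S1 against N1 were chosen only after the results were seen, and the others were set before.

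Rising and falling genes did not move in step. In N4 the genes that fall over the normal course had covered 0.85 ± 0.019 of their way (progress index, SD, n = 3), and the genes that rise had covered 0.37 ± 0.031. The same order was seen in super ovaries, at 0.68 ± 0.091 and 0.47 ± 0.074 in S7 and 1.01 ± 0.012 and 0.77 ± 0.020 in S8. Rescaling narrowed the gap and kept its direction, at 0.72 and 0.52 in N4, 0.67 and 0.49 in S7, and 0.94 and 0.85 in S8. Genes limited to a single stage, with at least 10 RPM there and under 1 RPM in all other stages of the course, were found mainly at flowering. There were 29 of them in the normal and 9 in the super course, with 7 in both. The super course had more other groups to stay under 1 RPM in, S8 among them. The rule was thus stricter there, and the counts of the courses cannot be set against each other.

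The super groups did not follow the normal course at a fixed lag. A constant delay of 4 days would leave S5 at the index of N1, which is 0, and it stood at 0.29 ± 0.028. An even stretch of the days by 9 to 5 stays open, because the measures disagree: it puts S4 nearest to N3 and S7 to N4, and by correlation all 6 libraries of these groups, of 21 in the super course, were nearest to an earlier group (S4 narrowly, at 0.953 against 0.947), while by the index S7 (0.59) was closer to N4 (0.66) than to N3 (0.39) and S4 (0.20) lay about midway between N1 and N3, with all 3 S8 libraries closer to N5 than to N4, where the stretch puts them. The index gained per day in super ovaries was 0.38 ± 0.06 of that in normal ones from the green bud to the last green yellow bud (0.073 against 0.194) and 0.61 ± 0.04 from there to flowering (0.188 against 0.306), where an even stretch, interpolated linearly and flat before day 1, gives 0.44 and 0.54. The early and late ratios both use the S5 and N3 libraries, and on the index S1 lay near N1 and S9 near N5. A low early ratio thus goes with a high late one. Together they are 1 observation, S5 at 0.29 against N3 at 0.39, and their SDs are not independent. With rescaled values these ratios were 0.39 and 0.60, which argues against the deposited scaling as the source. A stronger slowing of the early phase than of the late phase may describe the order. It is a hypothesis found and tested on the same data, and an even stretch could replace it in part.

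The median gene was lower in N5 than in N1 by 0.30 on the log2 scale, which in RPM requires other genes to take a larger share. A few very abundant genes are argued against, because leaving out the 100 most abundant ones, which held 10% of reads in N1 and 12.4% in N5, left the median at -0.27 ± 0.03 (SD over pairs of libraries). Among 5 classes of genes by abundance, the most abundant held 65.5% of RPM in N1 and 71.4% in N5, with a median change of 0, and the medians of classes 2 and 3 from the low end were -0.62 and -0.44. Whether the amount of RNA per corolla changed with opening was not tested and stays open.

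The 235 genes that differed between S1 and N1 could reflect buds sampled at another point of the same course. Then their differences were predicted to run along or against the later changes, and 47.7% (112 of 235) had the opposite sign to their change from N3 to N5. The prediction was thus not met for changes after day 3. A small offset near day 1 stays open, because genes that change between N1 and N3 need not keep that direction from N3 to N5. A single divergent library is argued against, with 209 to 285 genes when each of the 6 was left out. A difference from the treatment itself, or from plants or harvests, stays open and was not tested.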
